A study of Mus musculus with 14 samples.

How the data were processed

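The series holds droplet single-cell RNA sequencing (Drop-seq, in which single cells are captured with barcoded beads) of tissue punches from the lateral hypothalamic area of male wild-type C57BL/6J mice. The mice had free access to a high fat diet or to a control chow matched to it in taste, and each of the 14 libraries came from 1 mouse. Control mice and high fat diet mice numbered 7 each, and the replicate numbers used here follow the order in which the mice are listed within their diet. Per the labels, the libraries were sequenced as a pair of pools on separate lanes, with 4 mice of each diet in pool 1 and 3 of each in pool 2. The replicate numbers do not pair the mice, so no paired test was made.

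The deposited values are raw counts of unique molecular identifiers (UMIs), 1 table of genes by cell barcodes per mouse, in whole numbers and with no normalization. Per the submitters' processing notes, bcl2fastq 2.18.0.12, STAR 2.4.2a and Picard 2.2.4 were used with the mouse build mm10 (GRCm38). The tool that counted UMIs, its gene annotation and the rule by which barcodes were kept are not given in the sources used here. Without the counting rule, genes that share sequence with a close copy, such as ribosomal protein genes and their pseudogenes, and genes that overlap on opposite strands have less certain counts than the rest. Gene positions were taken from GENCODE M21 on GRCm38 by symbol. Of the 21568 symbols in the tables, 20143 were found there and 20094 had 1 position.

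Barcodes were kept as cells with at least 500 UMIs, at least 300 genes and at most 20% of UMIs from mitochondrially encoded genes. Scrublet, as part of scanpy 1.11.5, was run on each mouse with at least 300 cells at an expected doublet rate of 5%, and the barcodes it called doublets were removed. Counts were scaled to a common total per cell and log transformed. The cells of all mice were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm (leidenalg 0.10.2) at resolution 1. A cluster was given the name of a cell class when at least 3 markers of that class, from lists fixed beforehand, were raised at least 1.5-fold over the other cells and seen in at least 10% of its cells. The class names used here therefore mean clusters that resemble those classes by these markers. Neurons were clustered again in the same way, and their subclusters were divided into glutamatergic neurons, GABAergic neurons, hypocretin neurons, neurons with melanin-concentrating hormone (MCH) and neurons that met the markers of no class. Ependymal cells and tanycytes were not found among the clusters and were not tested. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and scikit-learn 1.9.0 were used.

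The mouse was the replicate throughout. Cells per mouse, UMIs per cell and the share of kept cells in each class were compared with a two-sided exact permutation test of the difference between diet means over all 3432 ways to choose 7 of 14 mice, on log10 values for cells and UMIs and on percentages for shares, with Benjamini-Hochberg adjustment over classes. For gene tests, counts were summed over the cells of a class in each mouse that had at least 10 of them, and a class was tested when at least 3 mice of each diet did. The sums were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, robust fit, TMM scaling, filterByExpr) with sequencing pool as a covariate, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Unless said otherwise, CPM take as their total the UMIs of the genes that passed the filter, after TMM scaling. These genes held 95.9 to 98.8% of UMIs in neurons and oligodendrocytes and 29.3 to 57.3% in the other classes, where these CPM exceed CPM of all UMIs. The difference between the diet effects of glutamatergic and GABAergic neurons was tested as an interaction with the mouse as a block. Neuron subclusters were tested in the same way as classes, with the adjustment over all genes and subclusters together. Gene lists fixed beforehand, and the markers of other cell types, were tested with the camera function of limma 3.58.1 at a preset correlation between genes of 0.01 where at least 5 members were measured, with adjustment over the lists of a class. Camera asks whether the members of a list moved more in 1 direction than the other measured genes did. Calls were set beside those of camera with an estimated correlation and of the rotation test fry. For the ribosomal, mitochondrially encoded and nuclear respiratory lists that passed, camera was run again after a smooth trend over GC content and transcript length was taken from each library.

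The genes named were chosen by a rule. In each class it takes up to 12 genes in each direction among those that pass, or, where fewer than 5 pass, the 5 with the smallest p in each direction. It adds 10 genes fixed for the neuron classes and the 4 members with the smallest p of each list that passed. Some members of lists are given only through their list, and 1 further gene that the rule takes is not reported here. The tests, this rule, the gene lists and most alternatives were written down before the data were examined. The alternatives were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors, no filter on low counts, no covariate, other UMI minimums (1000 and 300), resolutions of 0.5 and 2, doublets kept, at least 30 cells per mouse, counts thinned to equal totals, fits without the 3 mice under 500 cells and fits without each mouse in turn. A term for control replicates 1 and 2 and high fat diet replicate 1, fits without those 3 mice, fits without barcodes holding more marker UMIs of another class than of their own, and fits of neuron subclusters without each mouse in turn were chosen after seeing the data.

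The gene test was tested on simulated counts drawn from the real means and library totals with a known set of genes changed. It called 76.1% of the genes changed 2-fold in glutamatergic neurons, 77.6% in GABAergic neurons, 79.1% in oligodendrocytes, 86.4% in astrocytes, 80% in microglia, 73.1% in oligodendrocyte precursor cells (OPCs), 44.9% in endothelial cells and 44.4% in mural cells. The set changed was 200 genes, of 8661 in glutamatergic neurons, 9431 in GABAergic neurons, 6073 in oligodendrocytes and 1301 in OPCs. It was 133 of 665 in astrocytes, 104 of 523 in microglia, 147 of 739 in endothelial cells and 53 of 266 in mural cells. A larger changed share eases the adjusted threshold, so these percentages do not rank the classes. They can overstate power where few genes change. In endothelial cells 10.8% of the calls of the test were false, against 1.59 to 5.34% in the other classes. For the difference between neuron classes it called 76.1% of genes set 2-fold apart. In simulated classes with 1 list raised 1.3-fold, that list was called in 6 of 6, beside 1 of 114 other lists. Many of the lists called in Results had smaller median changes, and how often changes of their size would be called was not simulated. The simulated genes varied independently of each other, so these simulations say nothing about lists whose members vary together between mice. Total counts ran from 147470 to 5611524 UMIs per mouse, and the sums per mouse and class are given with each comparison, since they set the precision of each value. Figures were drawn with matplotlib 3.10.9.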

Results

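Single-cell transcriptomes were collected by Drop-seq from lateral hypothalamic area punches of 7 male mice given free access to a control chow and 7 given a high fat diet. The lateral hypothalamic area mixes glutamatergic and GABAergic neurons with glia and vessels, and the series title concerns a population there that restrains feeding and its transcriptional state in obesity. The tables of the 14 mice held 28410 barcodes and 21568 gene symbols. Of these barcodes 15378 passed the filters, 214 (1.39%) were removed as doublets and 15164 cells were kept. The median kept cell had 1337.5 UMIs and 819 genes, with 3436 UMIs in the median neuron and 994 in the median other cell. Depth was uneven between mice. The total ran from 147470 UMIs in high fat diet replicate 7 to 5611524 in high fat diet replicate 2, and kept cells ran from 49 in high fat diet replicate 7 to 1753 in control replicate 4. Control replicates 6 and 7, with 149 and 217 kept cells, were also small.

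Depth did not separate the diets. A control mouse gave 1066 ± 642 kept cells (SD, n = 7) and a high fat diet mouse 1100 ± 624 (n = 7), and the ratio of geometric means, high fat diet over control, was 0.970 (two-sided exact permutation p = 0.972 on log10 values). Median UMIs per cell were 1399 ± 321 (SD, n = 7) in control mice and 1364 ± 235 (n = 7) in high fat diet mice (exact permutation p = 0.881 on log10 values). Within pool 1 the means were 980 and 1212 kept cells with a ratio of geometric means of 0.837, and within pool 2 they were 1181 and 952 with a ratio of 1.18 (exact permutation p = 1.0 on log10 values in each pool).

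The cells formed 21 clusters, and the 6191 neurons among them formed 30 subclusters. Oligodendrocytes, the myelin-forming glia, were the most abundant class, with 42.9 ± 8.20% of kept cells in control mice and 39.1 ± 5.29% in high fat diet mice (SD, n = 7 each). Neurons made up 35.7 ± 12.6% of cells in control mice and 41.7 ± 11.0% in high fat diet mice (SD, n = 7 each; exact permutation p = 0.365). GABAergic neurons held 15.6 ± 7.80% and 18.9 ± 7.61% of cells, glutamatergic neurons 10.5 ± 3.60% and 11.5 ± 5.89%, and neurons that met the markers of no class 7.87 ± 3.06% and 10.2 ± 3.99%. Astrocytes held 6.79 ± 1.93% and 6.81 ± 4.06%, OPCs 4.44 ± 1.65% and 3.40 ± 0.951%, endothelial cells 3.86 ± 2.38% and 3.44 ± 3.09%, microglia 3.04 ± 1.20% and 3.08 ± 0.998%, and mural cells, the contractile cells around vessels, 2.51 ± 1.01% and 1.81 ± 1.17%. Hypocretin neurons, which promote wakefulness, held 1.13 ± 0.854% of cells in control mice and 0.838 ± 0.610% in high fat diet mice. MCH neurons, named for a peptide that promotes feeding, held 0.620 ± 0.427% and 0.283 ± 0.277%. Fibroblasts held 0.363 and 0.444%, newly formed oligodendrocytes 0.165 and 0.203%, and perivascular macrophages 0.150 and 0.105%.

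No class passed the test of a difference in its share between diets. The lowest exact permutation p, for MCH neurons, was 0.101, and the adjusted p over the 14 classes was at least 0.899. Within the pools the same MCH comparison had an exact permutation p of 0.343 (0.483% against 0.259%) and 0.3 (0.804% against 0.314%). Oligodendrocytes held 44.2% against 37.2% in pool 1 (exact permutation p = 0.286) and 41.2% against 41.5% in pool 2.

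**Figure D1:**
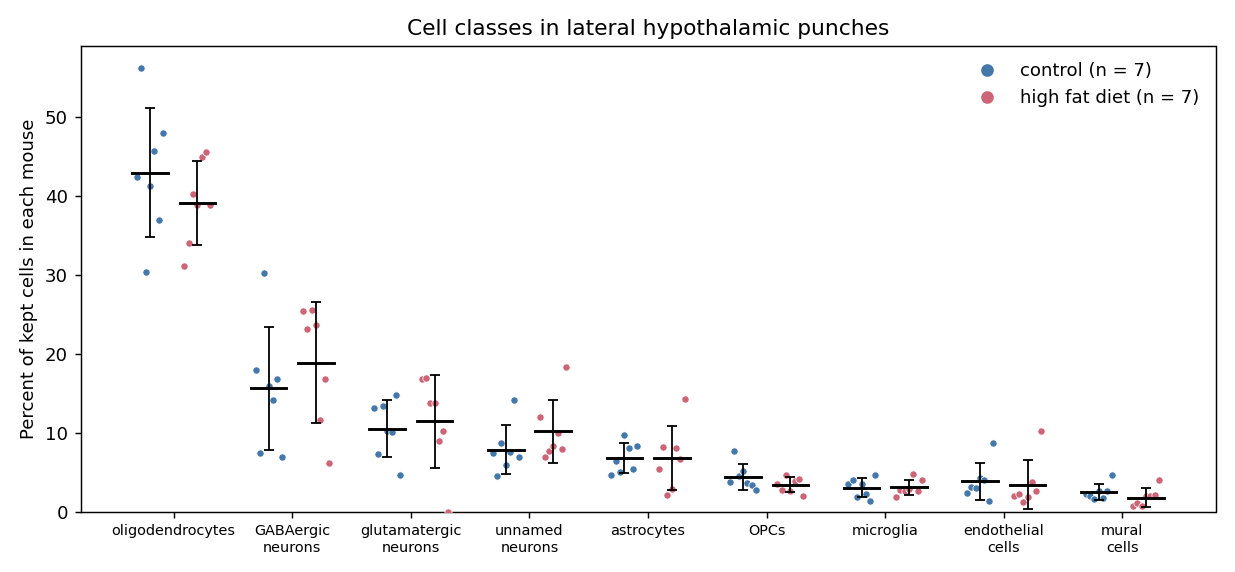
Percent of kept cells in each of 9 classes, with 1 point per mouse (7 control, 7 high fat diet), the mean as a bar and the SD as an error line. The diets overlap in every class shown, and the 14.3% of astrocytes and 10.2% of endothelial cells at the top of their classes belong to high fat diet replicate 7, which kept 49 cells.

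Control replicates 1 and 2 and high fat diet replicate 1 stood apart from the other 11 mice in both glia and neurons. From 55.0 to 70.9% of their oligodendrocytes fell in a single cluster that held 0 to 15.2% of oligodendrocytes in the others. From 35.8 to 44.5% of their neurons fell in a pair of subclusters that held 0 to 2.43% in the others. The labels number these 3 mice 1 to 3 and place all of them in pool 1, with other mice that did not stand apart. No label names a batch for them, and they include both diets. Values within pool 1 therefore hold these 3 mice, and values within pool 2 do not.

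Glutamatergic neurons are marked by Slc17a6, the vesicular glutamate transporter that loads their synaptic vesicles. Slc17a6 stood at 1173 ± 257 CPM in control mice (SD, n = 7) and 1082 ± 216 CPM in high fat diet mice (n = 6), a log2 fold change of −0.11 (SE 0.14). Fos, an immediate early gene that neuronal activity can raise, had a log2 fold change of −0.62 (SE 0.56), and Insr, the insulin receptor, −0.46 (SE 0.42). The neuropeptide genes Hcrt, Pmch, Nts and Gal lay between −0.56 and −0.16, and Slc32a1, the vesicular GABA transporter, at −0.85. Hypocretin and MCH neurons were classes of their own and were not tested for genes, so Hcrt and Pmch here come from cells placed outside them. Lepr and Mc4r, the leptin and melanocortin 4 receptors, were under the filter on low counts in both neuron classes. The sums held 65689 to 1659260 UMIs per mouse over 1864 cells.

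No glutamatergic gene passed the test of diet. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment the count was 0 of 8661 genes, with 132 at an unadjusted p under 0.05, and DESeq2 and limma voom with quality weights each gave 0. The genes with the smallest p, none of which passed, were Sfrp2, an extracellular antagonist of Wnt signalling (log2 fold change 1.13), Fsd1 (0.54), Rftn1 (0.65), Nle1 (0.92) and 9330158H04Rik (0.94) on the higher side. On the lower side they were Sox2, a transcription factor of neural progenitors, at −1.63 (20.3 ± 9.69 CPM in control mice and 5.81 ± 4.48 in high fat diet mice, SD), Nhlrc2 (−1.16), Elovl4, an elongase of very long chain fatty acids (−0.54; 129 ± 20.3 and 83.1 ± 10.7 CPM), Cpsf4 (−0.97) and Dnajc13 (−0.76).

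As groups, the subunits of GABA-A receptors were lower in glutamatergic neurons of high fat diet mice. These receptors carry fast synaptic inhibition, 11 of 12 measured members were lower, and the median log2 fold change was −0.20 (camera adjusted p = 0.00237). The call was lost with an estimated correlation (adjusted p = 0.62 with an estimated correlation), and the medians within pools 1 and 2 were −0.32 and −0.05. Gabrg1 was at −0.39, Gabra4 at −0.38, Gabra2 at −0.28 and Gabra5 at −0.26, and none passed alone. Genes of mitochondrial respiration split by genome in these neurons. Nuclear-encoded complex I subunits were higher (28 of 36, median 0.07, camera adjusted p = 0.00237), as were subunits of complexes III, IV and ATP synthase (27 of 33, median 0.08, adjusted p = 0.0248), and both were lost with an estimated correlation (adjusted p = 0.756 with an estimated correlation). Mitochondrially encoded genes were lower (10 of 10, median −0.20, adjusted p = 0.0102), and so were cytosolic ribosomal protein genes (29 of 40, median −0.09, adjusted p = 0.015). These calls were lost as well (adjusted p = 0.756 with an estimated correlation). After a correction for GC content and transcript length the ribosomal list passed and the other 3 did not (adjusted p = 0.0708, 0.111 and 0.111, with 87.8, 78.0 and 73.5% of the medians left). In pool 2 alone both nuclear lists had negative medians (−0.14 and −0.07, against 0.21 and 0.22 in pool 1), and both calls ended without high fat diet replicate 3 (adjusted p = 0.702 and 0.904). Without control replicate 2 the mitochondrially encoded and ribosomal calls ended (adjusted p = 0.174 and 0.462). Of the 13 sets that leave out 1 mouse, complex I lost its call in 4, complexes III, IV and ATP synthase in 7, mitochondrially encoded genes in 5 and ribosomal genes in 4. Neuropeptides (median −0.08, adjusted p = 0.504), feeding hormone and peptide receptors (−0.15, 0.21), leptin and insulin signalling (−0.04, 0.972), synaptic vesicle release (−0.03, 0.972), glutamate receptors (−0.03, 0.213) and immediate early genes (−0.02, 0.476) did not pass.

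In GABAergic neurons the gene with the smallest p was Grp, which encodes gastrin-releasing peptide. It stood at 12.8 ± 6.92 CPM in control mice (SD, n = 7) and 36.5 ± 14.3 CPM in high fat diet mice (n = 6), a log2 fold change of 1.84 (SE 0.31), with 6 of 6 high fat diet mice above the control mean. Rpph1, the RNA component of ribonuclease P, followed at 85.1 ± 17.3 and 168 ± 52.9 CPM, a log2 fold change of 1.02 (SE 0.19), again in 6 of 6 mice. Grp lies on the plus strand of chromosome 18 of GRCm38 from 65872820 to 65886596. The difference in mean log2 CPM was 1.97 in pool 1 and 1.08 in pool 2 for Grp, and 1.10 and 0.77 for Rpph1. The sums held 98828 to 2038420 UMIs per mouse over 2932 cells.

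By edgeR quasi-likelihood neither gene passed, with an adjusted p of 0.0525 for Grp and 0.0766 for Rpph1, and the count was 0 of 9431 genes, with 156 at an unadjusted p under 0.05. DESeq2 and limma voom with quality weights each called 2 genes, and both tools called Grp and Rpph1 higher. With a term for control replicates 1 and 2 and high fat diet replicate 1, chosen after seeing the data, both genes also passed by edgeR (adjusted p = 0.00271 each, log2 fold change 1.82 and 1.03), but without these 3 mice 0 genes passed (Grp 1.76, adjusted p = 0.154, and Rpph1 0.83, 0.354). By edgeR 1 gene passed without high fat diet replicate 1 or 3, and 2 passed without high fat diet replicate 5. The other genes with the smallest p, which did not pass by edgeR, were Pou3f2, a neuronal transcription factor (log2 fold change 0.66), Aptx, a DNA repair enzyme (0.52), and A330069E16Rik (1.10) on the higher side. Cdk8 (−1.10), Agps (−0.76), Mgat5 (−0.87), Ttc17 (−0.66) and Pop1, a protein subunit of ribonuclease P (−0.80), were on the lower side. Slc32a1, which defines these neurons, had a log2 fold change of 0.04 (SE 0.13) at 667 ± 121 and 683 ± 97.3 CPM (SD). Fos was at 0.39 (SE 0.21), Slc17a6 at 0.30, Gal at 0.15, Hcrt at −0.23, Nts at −0.39, Insr at −0.41 and Pmch at −0.45, and none of them passed. As in glutamatergic neurons, Hcrt and Pmch were counted here outside the hypocretin and MCH classes.

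The gene lists that moved in GABAergic neurons were complex I subunits (33 of 36 higher, median log2 fold change 0.09, camera adjusted p = 0.000183) and complexes III, IV and ATP synthase (29 of 33 higher, median 0.08, adjusted p = 0.00478). These and the 6 other calls of the class were all lost with an estimated correlation (adjusted p = 0.545 with an estimated correlation). After a correction for GC content and transcript length complex I (adjusted p = 0.134, 43.7% of the median left) and complexes III, IV and ATP synthase (0.426, 35.8%) did not pass either, nor did mitochondrially encoded genes (0.0878, 92.5%). Cytosolic ribosomal protein genes were lower (36 of 42, median −0.11, adjusted p = 0.000183), led by Rps15 (−0.35), Rplp1 (−0.33) and Rpl35 (−0.52). A further 5 lists shared an adjusted p of 0.0484. Of these, glucocorticoid-responsive genes were higher (8 of 12, median 0.23), with Cdkn1a at 0.81, Nfkbia at 0.36, Ddit4 at 0.35 and Tsc22d3 at 0.26, and so were lipid handling genes (11 of 13, median 0.12), with the cholesterol transporter Npc1 at 0.40 and the lipid carrier Clu at 0.24. Myelin genes were also higher (8 of 11, median 0.24), beside markers of oligodendrocytes measured in the same neurons (5 of 7 higher, median 0.28, adjusted p = 0.076). Mitochondrially encoded genes (8 of 10, median −0.19) and GABA-A receptors (11 of 12, median −0.15) were lower. The makeup of the class by subcluster varied widely between mice, and subcluster 2 held 11.8 ± 14.7% of GABAergic neurons in control mice (SD, n = 7) and 19.7 ± 15.9% in high fat diet mice (n = 6; exact permutation p = 0.361, adjusted over 8 subclusters 0.941). In pool 2 alone the medians of complex I (−0.13), complexes III, IV and ATP synthase (−0.03) and GABA-A receptors (0.15) had the opposite sign, and without high fat diet replicate 3 every list but the ribosomal one lost its call (adjusted p from 0.128 to 0.738). Of 13 sets that leave out 1 mouse, glucocorticoid, lipid and GABA-A lists lost their calls in 9, myelin and mitochondrially encoded genes in 6 and the nuclear respiratory lists in 2, and without control replicate 3 the myelin list had an adjusted p of 0.962. Neuropeptides (median 0.07, adjusted p = 0.303), feeding hormone and peptide receptors (−0.05, 0.951), leptin and insulin signalling (0.00, 0.87), synaptic vesicle release (0.01, 0.87), glutamate receptors (−0.02, 0.87) and immediate early genes (−0.06, 0.933) did not pass.

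**Figure D2:**
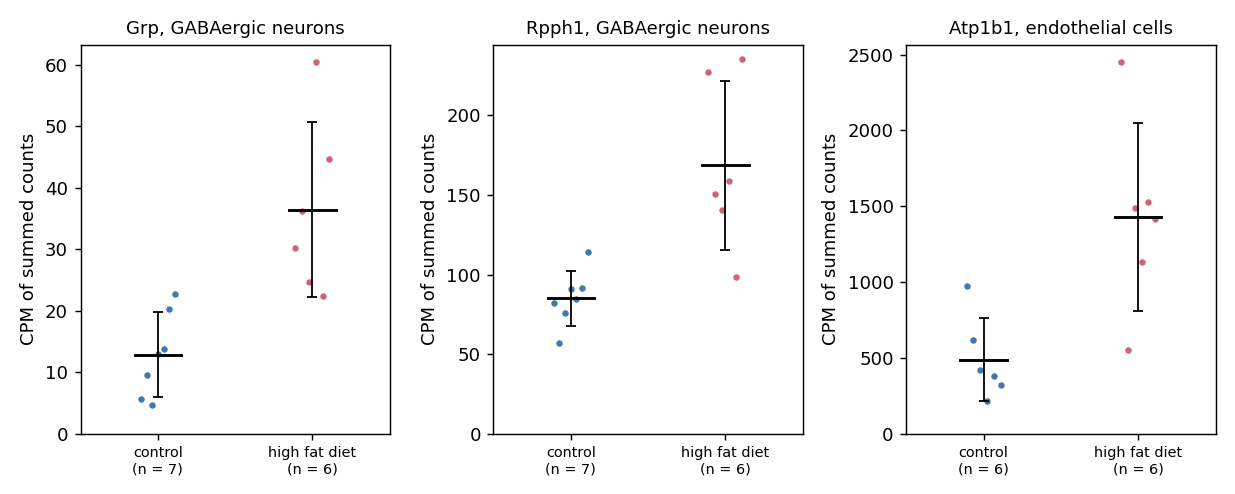
CPM of summed counts, over the genes tested in each class, of Grp and Rpph1 in GABAergic neurons and of Atp1b1 in endothelial cells, with 1 point per mouse, the mean as a bar and the SD as an error line. Grp averages 12.8 CPM in 7 control mice and 36.5 CPM in 6 high fat diet mice, and Atp1b1 489 CPM and 1428 CPM in 6 mice of each diet.

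Ecel1, which encodes an endothelin-converting enzyme-like peptidase of neurons, was the gene whose diet difference differed between the neuron classes. In glutamatergic neurons it stood at 20.9 ± 13.9 CPM in control mice (SD, n = 7) and 12.4 ± 7.22 CPM in high fat diet mice (n = 6), a log2 fold change of −0.90 (SE 0.35). In GABAergic neurons it stood at 189 ± 107 and 199 ± 66.7 CPM, a log2 fold change of 0.17 (SE 0.32). The test of the difference gave −1.15 on the log2 scale (SE 0.24, edgeR quasi-likelihood adjusted p = 0.0406), the single gene to pass of 9326 tested, with 345 at an unadjusted p under 0.05. Ecel1 is named here after its values were seen. Both pools had the glutamatergic difference in mean log2 CPM below the GABAergic one, at 0.66 against 0.90 in pool 1 and −2.09 against −0.58 in pool 2. By this measure both classes were higher on the high fat diet in pool 1 and lower in pool 2, and they lay further apart in pool 2. The call ended, with 0 genes passing, when any 1 of control replicates 1, 3 and 5 or high fat diet replicates 1, 2, 3, 4 and 6 was left out.

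Among neuron subclusters, diet was tested in 11 with enough cells, over 33810 pairs of gene and subcluster. Penk, the precursor of enkephalin opioid peptides, rose in GABAergic subcluster 3, whose leading genes are Pgr15l, Ecel1, Hmx3 and Gal. It stood at 227 ± 93.7 CPM in control mice (SD, n = 4) and 448 ± 148 CPM in high fat diet mice (n = 6), a log2 fold change of 1.11 (SE 0.19, edgeR quasi-likelihood adjusted p = 0.0244). Scg2, secretogranin II of dense-core vesicles, fell in glutamatergic subcluster 9, whose leading genes are Fezf2, Fst, Mab21l1 and Samd3. It stood at 3424 ± 700 CPM in control mice (SD, n = 3) and 1898 ± 283 CPM in high fat diet mice (n = 4), a log2 fold change of −0.84 (SE 0.15, edgeR adjusted p = 0.0244). These 2 pairs passed of 33810, with 1063 at an unadjusted p under 0.05, and both genes are named after their values were seen. The difference in mean log2 CPM of Penk was 1.11 in pool 1 and 0.84 in pool 2, and that of Scg2 was −1.04 in pool 1, which holds 1 control mouse with enough cells, and −0.74 in pool 2. Penk lost its call without control replicate 1, 3 or 4 or high fat diet replicate 2 (adjusted p = 0.051, 0.33, 0.293 and 0.183), and Scg2 without control replicate 3 or 4 or high fat diet replicate 6 (adjusted p = 1.0, 0.409 and 0.176). Without control replicate 1 Scg2 kept its fold change and SE, and the adjustment over all pairs alone took it to an adjusted p of 0.051. From 0 pairs, without control replicate 1, to 8 pairs, without high fat diet replicate 1, passed when 1 mouse was left out, with 4 without high fat diet replicate 2 or control replicate 5, 6 without high fat diet replicate 4 and 2 or 3 without each of the others.

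Oligodendrocytes gave the largest sample, with 6176 cells and 7 mice of each diet, and their 18 measured myelin genes, whose products form the sheath around axons, did not pass as a list (median log2 fold change −0.03, camera adjusted p = 0.739). Glucocorticoid-responsive genes were lower in them on the high fat diet, 11 of 11 members with a median of −0.26 (adjusted p = 0.000151; adjusted p = 0.75 with an estimated correlation). The call rested on control replicate 5, without which its adjusted p was 0.802 and its median 0.01, and the median was 0.08 in pool 1 and −0.68 in pool 2. Sgk1, a kinase induced by glucocorticoids, was at −1.83, the transcription factor Zbtb16 at −1.03, the metallothionein Mt2 at −0.77 and the transcription factor Klf9 at −0.54. Mitochondrially encoded genes (10 of 10, median −0.24, adjusted p = 0.00011) and cytosolic ribosomal protein genes (24 of 33, median −0.11, adjusted p = 0.0121) were lower too, and both calls were lost with an estimated correlation (adjusted p = 0.595 and 0.75 with an estimated correlation). Within pools 1 and 2 the medians were −0.33 and −0.02 for mitochondrially encoded genes and −0.11 and 0.09 for ribosomal genes. Oligodendrocyte clusters also varied widely between mice, with cluster 1 holding 31.1 ± 25.3% of the class in control mice and 34.2 ± 23.2% in high fat diet mice (SD, n = 7 each; exact permutation p = 0.815). The ribosomal call ended in 6 of 14 sets that leave out 1 mouse, with the highest adjusted p without control replicate 2 (0.614). Without control replicates 1 and 2 and high fat diet replicate 1 the mitochondrially encoded call ended (adjusted p = 0.144).

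No single oligodendrocyte gene passed by edgeR quasi-likelihood, 0 of 6073, with 118 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma voom with quality weights. The smallest p belonged to Pcp4, a calmodulin regulator (log2 fold change 0.88), Tmed3 (0.48), Cdc42se2 (0.40), Cactin (0.82) and Bfsp2 (0.51) among higher genes, and to Plekhf1 (−1.07), the nuclear import receptor Kpnb1 (−0.63), Azin1 (−0.73), Gmps (−0.66) and Ranbp9 (−0.91) among lower genes. The sums held 46179 to 1125010 UMIs per mouse.

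In OPCs, the dividing precursors of oligodendrocytes, the mitochondrially encoded genes were lower on the high fat diet, 7 of 7 with a median log2 fold change of −0.26 (camera adjusted p = 0.00598; adjusted p = 0.39 with an estimated correlation). mt-Nd5 was at −0.84 and mt-Rnr2 at −0.83. Immediate early genes had a median of −0.31, with 6 of 9 lower, and did not pass (adjusted p = 0.0834). Fosb, a member of that list, was at −1.22 (3729 ± 1208 CPM in 5 control mice and 1572 ± 792 CPM in 6 high fat diet mice, SD) and was the single gene lower in that list adjusted over the list alone. Of 1301 genes 0 passed by edgeR quasi-likelihood, DESeq2 and limma voom with quality weights, with 48 at an unadjusted p under 0.05 by edgeR. The smallest p belonged to the splicing factor Srsf3, at −1.14 (edgeR adjusted p = 0.318, lower in 6 of 6 high fat diet mice), Gpld1 (−0.69), Ash1l (−0.74), Pou3f1, a transcription factor of myelinating glia (1.09), Cmtm5 (0.82), Epdr1 (0.90), G0s2 (0.66) and Atp6v0d1 (0.74). OPC barcodes also held marker UMIs of other classes, which may be RNA of other cells or of the OPCs themselves. Barcodes with more marker UMIs of another class than of OPCs made up 15.1% of 365 in control mice and 19.4% of 273 in high fat diet mice (exact permutation p = 0.561 over mice), and neuron RNA was estimated at 13.2 ± 1.34% and 16.2 ± 2.06% of their UMIs (SD; exact permutation p = 0.0238, adjusted over 6 classes 0.0714). The sums held 24644 to 118499 UMIs per mouse. The mitochondrially encoded call ended without control replicate 2 (adjusted p = 0.109), and its median ran from −0.14 without high fat diet replicate 3 to −0.45 without control replicate 3.

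Astrocytes on the high fat diet had higher levels of nuclear-encoded respiratory genes as groups. Complex I subunits were higher in 15 of 20 members (median log2 fold change 0.20, camera adjusted p = 0.0188), with Ndufb7 at 0.57 and Ndufb6 at 0.53, and complexes III, IV and ATP synthase in 21 of 27 (median 0.10, adjusted p = 0.0498). Both were lost with an estimated correlation (adjusted p = 0.577 with an estimated correlation), and without high fat diet replicate 3 (adjusted p = 0.146 and 0.343), with 6 and 10 of 12 calls lost when 1 mouse was left out. A correction for GC content and transcript length also ended both (adjusted p = 0.589 and 0.694), with 54.4 and 30.2% of the medians left. The medians in pool 2 were 0.02 and −0.01. Genes by which astrocytes handle glutamate, water and lactate were lower in 12 of 14 members (median −0.08) and did not pass (adjusted p = 0.165). By edgeR quasi-likelihood 0 of 665 genes passed, with 19 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma voom with quality weights. The smallest p belonged to Tmbim6, a regulator of calcium in the endoplasmic reticulum (0.65), Minos1 (0.67), Tmem176a (0.73), Chst1 (0.64), the brain fatty acid-binding protein Fabp7 (0.61), Ttc14 (−0.66), mt-Nd5 (−0.49), Ece1 (−0.62), Hsd11b1, which regenerates active glucocorticoid (−0.80), and Tmod2 (−0.63). The sums held 21571 to 129799 UMIs per mouse over 906 cells.

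Microglia, the resident macrophages of the brain, had lower levels of mitochondrially encoded genes, 7 of 7 with a median log2 fold change of −0.55 (camera adjusted p = 0.000331), with mt-Nd5 at −0.81 and mt-Nd2 at −0.51. Cytosolic ribosomal protein genes were lower in 18 of 23 members (median −0.19, adjusted p = 0.0421). With an estimated correlation the adjusted p were 0.22 and 0.565 (adjusted p with an estimated correlation). Within pools 1 and 2 the medians were −0.34 and −0.44 for the former list and −0.46 and 0.11 for the latter, whose call also ended without control replicate 2 (adjusted p = 0.358) and in 5 of the 12 sets that leave out 1 mouse. Without high fat diet replicate 2 or 3 the median of mitochondrially encoded genes was −0.17 or −0.33. Homeostatic genes (12 measured, median 0.06, adjusted p = 0.727) and genes of activation and inflammation (median −0.05, adjusted p = 0.397) did not pass. By edgeR quasi-likelihood 0 of 523 genes passed, with 16 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma voom with quality weights. The smallest p belonged to the Fc receptor Fcgr3 (0.54), Camk1 (1.03), the fructose transporter Slc2a5 (0.71), Abi3 (0.70), Gpr34 (0.44), Ccnl1 (−0.61), Krcc1 (−0.77) and Ier3 (−0.50). The sums held 13998 to 64812 UMIs per mouse over 443 cells.

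Summed over endothelial barcodes Atp1b1, the beta subunit of the sodium-potassium pump, rose on the high fat diet, but 6 of 167 high fat diet barcodes, from 4 mice and with more neuron than endothelial marker UMIs, held 65.7% of its UMIs. Without barcodes holding more marker UMIs of another class than of endothelial cells its log2 fold change was −0.12 (SE 0.42, with no filter on low counts). Over all barcodes it stood at 489 ± 273 CPM of the tested genes in control mice (SD, n = 6) and 1428 ± 619 CPM in high fat diet mice (n = 6), or 240 ± 130 and 681 ± 291 CPM of all endothelial UMIs, a log2 fold change of 1.75 (SE 0.31, edgeR quasi-likelihood adjusted p = 0.0059), with 6 of 6 high fat diet mice above the control mean. Atp1b1 lies on the minus strand of chromosome 1 of GRCm38 from 164437109 to 164458355. It was the single gene to pass of 739 tested, with 74 at an unadjusted p under 0.05, and DESeq2 and limma voom with quality weights each called Atp1b1 and Rtn4. The difference in mean log2 CPM was 1.54 in pool 1 and 1.82 in pool 2. Neuron RNA moved with it, at an estimated 6.56 ± 3.09% of endothelial UMIs in control mice and 16.3 ± 8.60% in high fat diet mice (SD, n = 6 each; exact permutation p = 0.0152, adjusted over 6 classes 0.0714). Without the barcodes richer in markers of another class 0 genes passed, and 0 passed with a minimum of 300 UMIs, with doublets kept, at a resolution of 2 or with at least 30 cells per mouse. Leaving out control replicate 3 gave 7 genes and leaving out high fat diet replicate 6 gave 1, with 2 to 6 genes without each of the others. The sums held 20569 to 101359 UMIs per mouse over 429 cells.

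Rtn4, a myelin-associated inhibitor of axon growth, had a log2 fold change of 1.19 and did not pass by edgeR (adjusted p = 0.0519), but passed by DESeq2 (0.0317), by limma voom with quality weights (0.0407) and with DESeq2 size factors (0.0481). Other genes that followed Atp1b1 without passing by edgeR were the glycolytic enzyme Aldoa (1.05, 0.127), the mitochondrial ADP/ATP carrier Slc25a4 (0.88) and Ndufb10 (0.94). On the lower side were the stress-induced transcription factor Atf3 (−1.44, edgeR adjusted p = 0.0913), Ahnak (−1.02), the cell cycle inhibitor Cdkn1a (−0.89), Utrn (−0.74) and the metallothionein Mt1 (−1.10). All of these values come from fits that held the barcodes richer in markers of another class, without which 0 endothelial genes passed by edgeR.

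Endothelial cells had 7 list calls, next to the 8 of GABAergic neurons. Complex I subunits were higher in 15 of 16 members (median log2 fold change 0.42, camera adjusted p = 9.46e-06), complexes III, IV and ATP synthase in 20 of 22 (median 0.36, adjusted p = 0.00014) and glycolysis in 4 of 5 (median 0.52, adjusted p = 0.0304), the last led by Aldoa and by Slc16a1, a monocarboxylate transporter (1.21). All 3 were lost with an estimated correlation (adjusted p = 0.121 with an estimated correlation). Adjusted over the list alone, 1 complex I subunit and 2 glycolysis genes were higher. Markers of other cells moved with them, with 10 of 10 neuron markers (median log2 fold change 1.23) and 10 of 10 oligodendrocyte markers (1.69) higher, and the neuron RNA estimate came to 105% of the rise of complex I counts. Lower lists were glucocorticoid-responsive genes (5 of 5, median −0.66, adjusted p = 0.00259), cytosolic ribosomal proteins (19 of 20, median −0.16, adjusted p = 0.00717), immediate early genes (10 of 10, median −0.30, adjusted p = 0.0238) and barrier and transport genes (9 of 10, median −0.30, adjusted p = 0.0322). These were lost too, at 0.222 for the glucocorticoid list, 0.121 for the ribosomal list, 0.383 for immediate early genes and 0.267 for the barrier list (adjusted p with an estimated correlation). Adjusted over the list alone, 3 glucocorticoid-responsive genes were lower (Cdkn1a, Mt1 and Tsc22d3), and in the barrier list 1 gene was lower, Abcb1a, the drug efflux pump (−0.65), and 1 was higher, Slc16a1. The glucose transporter Slc2a1 was at −0.48 and the organic anion transporter Slco1a4 at −0.49. In both pools the median of each of the 7 lists had the sign of its call, but 4 of the calls did not hold without each mouse in turn. The glycolysis call ended in 7 of 12 sets, without control replicates 1 to 4 or high fat diet replicates 1, 4 or 5 (camera adjusted p up to 0.129). The immediate early call ended in 4, without high fat diet replicate 1 (adjusted p = 0.458) or 2 (0.107) or control replicate 4 (0.249) or 7 (0.0513), the glucocorticoid call without control replicate 5 (0.0828) and the barrier call without control replicate 4 (0.152). Without barcodes holding more marker UMIs of another class, none of the 5 lists still measured passed (adjusted p from 0.181 to 0.84), with a median of 0.23 over the 8 complex I subunits left and 0.02 for complexes III, IV and ATP synthase.

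Mural cells gave no call for genes or lists in the fit with pool as covariate. By edgeR quasi-likelihood 0 of 266 genes passed, with 6 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma voom with quality weights. The smallest p belonged to Fosb (log2 fold change −1.22, edgeR adjusted p = 0.127, lower in 6 of 6 high fat diet mice) and Fos (−0.69), which were the 2 genes lower in the immediate early list adjusted over the list alone, and that list had 7 of 10 members lower (median −0.11, camera adjusted p = 0.0782). Fosb passed by edgeR with the term for control replicates 1 and 2 and high fat diet replicate 1 (adjusted p = 0.0312), without barcodes holding more marker UMIs of another class (0.0449), with at least 300 UMIs (0.0399), with no filter on low counts (0.04) and without control replicate 3 (0.0117) or high fat diet replicate 4 (0.0209). Without control replicates 1 and 2 and high fat diet replicate 1 it did not pass (adjusted p = 0.0702), and 0 mural genes did. Ttc3 (−0.84) and Adamts1 (−0.69) were also on the lower side, and the splicing factor Luc7l3 (0.88), the lysosomal protein Lamp1 (0.88), Psma7 (0.68), B2m (0.61) and Fermt2 (0.49) on the higher side. Endothelial markers measured in mural cells were higher in 5 of 5 members (median 0.47, adjusted p = 0.0782), and barcodes holding more marker UMIs of another class than of mural cells made up 11.1% of 162 in control mice and 23.5% of 102 in high fat diet mice (exact permutation p = 0.424 over mice). The sums held 7985 to 41421 UMIs per mouse over 258 cells.

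Over all classes, 28 of 138 tests of a list in a class passed, and the same lists recurred. The classes come from the same mice, so this recurrence is not independent. Other splits of the mice into groups of the same sizes gave a median of 17 calls. Mitochondrially encoded genes were lower in glutamatergic neurons, GABAergic neurons, oligodendrocytes, OPCs and microglia, and cytosolic ribosomal protein genes in both neuron classes, oligodendrocytes, microglia and endothelial cells. Nuclear-encoded respiratory genes were higher in both neuron classes, astrocytes and endothelial cells. Glucocorticoid-responsive genes were lower in oligodendrocytes and endothelial cells and higher in GABAergic neurons, and the difference between these classes was not tested. With an estimated correlation 0 of the 28 calls passed (adjusted p from 0.121 to 0.756), and by fry 4 did, all in endothelial cells. The median of the list had the sign of its call in both pools for 19 of the 28 calls. Without control replicates 1 and 2 and high fat diet replicate 1, 15 of the 28 were kept. Leaving out 1 mouse at a time, 7 of the 28 passed in every set, namely GABA-A receptors in glutamatergic neurons, ribosomal proteins in GABAergic neurons, mitochondrially encoded genes in oligodendrocytes and microglia, and complex I, complexes III, IV and ATP synthase and ribosomal proteins in endothelial cells. With barcodes holding more marker UMIs of another class removed from the non-neuronal classes, 21 of the 28 were kept, none in endothelial cells. The median of 24 of the 28 lists moved by over 1.5 times without at least 1 mouse, and that of glucocorticoid-responsive genes in oligodendrocytes changed sign.

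**Figure D3:**
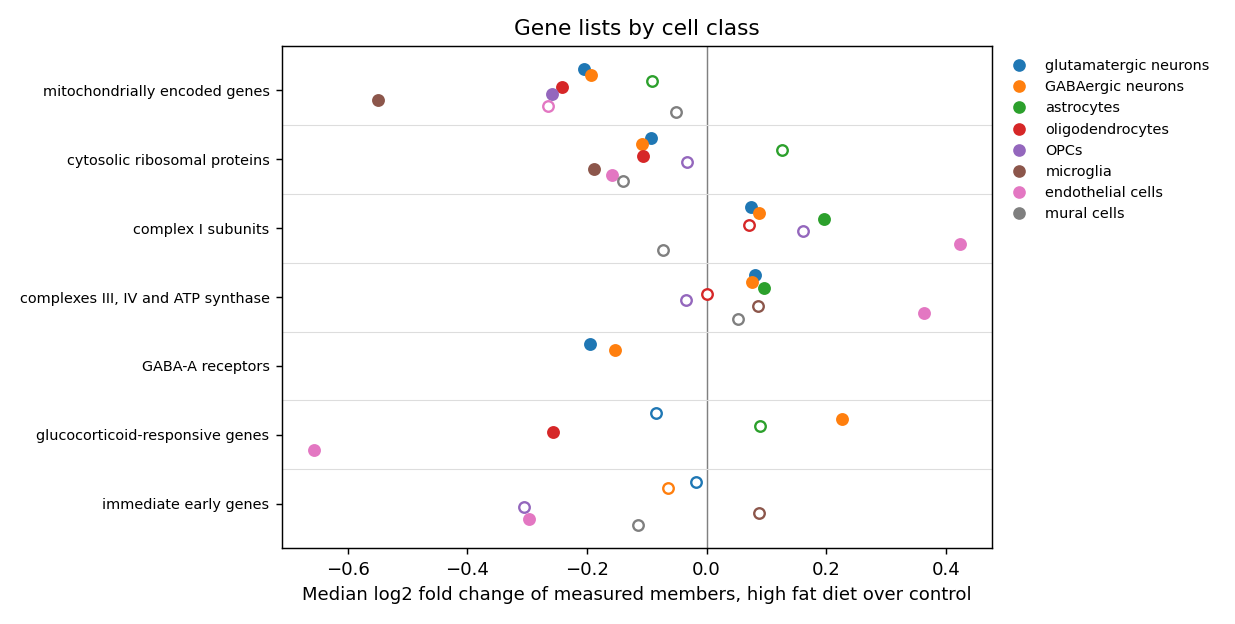
Median log2 fold change (high fat diet over control) of the measured members of 7 gene lists in each class, with filled points for lists that passed camera with a preset correlation and open points for those that did not. Filled points for mitochondrially encoded genes and ribosomal proteins all lie below 0, and those for complex I and for complexes III, IV and ATP synthase above 0.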

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

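Removing barcodes with more marker UMIs of another class, counting those richer in neuron markers mouse by mouse, reading the correction for GC content and length list by list, the splits counted apart for 3 mice, estimating Grp from the share of its subcluster and comparing Rpph1 across classes are the tests given here that were chosen only after the result was seen. Of 432 groups of 5 to 7 mice of the same diet, 46 (10.6%) held 1 mouse whose gap to its nearest neighbour was too large a part of the whole range by Dixon's 95% critical value. About 1 group in 20 passes that value by chance alone, and of the 37 such values that belong to single genes, 14 come from control replicate 6, which kept 149 cells. Depth set 3 values apart, the log10 of total UMIs (5.17) and of kept cells (1.69) of high fat diet replicate 7 and the log10 of median UMIs (3.27) of high fat diet replicate 2. Shares of cells set 6 apart. Control replicate 7 held 8.76% endothelial cells, 4.61% mural cells and 0.461% perivascular macrophages, and high fat diet replicate 7, with 49 cells, held 10.2% endothelial cells, 4.08% mural cells and 2.04% fibroblasts.

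The single genes were far from the other mice of the diet in log2 CPM. In GABAergic neurons control replicate 6 stood at −1.07 for Cdk8, Insr and Pop1, where it had no counts, and at 6.94 for Scd2. Control replicate 2 stood at 4.60 and high fat diet replicate 3 at 2.04 for Mgat5, control replicate 7 at 4.54 for Tsc22d3, high fat diet replicate 5 at 7.43 for Gal and high fat diet replicate 1 at 8.88 for mt-Co1. In glutamatergic neurons control replicate 6 stood at −0.48 for Cpsf4, Gal and Nle1, where it had no counts, at 9.02 for Fos, 4.60 for Ndufs3, 8.02 for Pmch and 9.05 for Rplp1. For Slc32a1 control replicate 7 stood at −0.48, also with no counts, and high fat diet replicate 2 at 2.90. For Atp5k high fat diet replicate 5 stood at 8.45. In oligodendrocytes control replicate 6 stood at 4.46 for Azin1 and at −0.11 for Rpl7 and Rpl30, high fat diet replicate 7 at −0.11 for Rpl30 and high fat diet replicate 1 at 3.90 for Cactin. The values of −0.11 again mean no counts. In astrocytes control replicate 7 stood at 11.64 for Cox4i1 and 10.03 for Ece1, control replicate 1 at 9.84 for Tmbim6 and high fat diet replicate 1 at 4.02 for Hsd11b1. In endothelial cells control replicate 5 stood at 11.13 for Ahnak, control replicate 2 at 10.68 for Klf4, control replicate 1 at 13.08 for Slco1a4 and high fat diet replicate 1 at 8.28 for Cox5a and 11.80 for Jun. In microglia high fat diet replicate 1 stood at 4.61 for Camk1, control replicate 4 at 7.90 for Rpl23 and control replicate 3 at 10.25 for mt-Nd2, and in mural cells high fat diet replicate 2 stood at 9.69 for Psma7.

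Ecel1 differed between the neuron classes in its diet difference, by −1.15 on the log2 scale (edgeR adjusted p = 0.0406). Of 100 splits of the mice, the real one included, 20 gave at least 1 such gene and the highest other gave 4, so chance is not excluded. Control replicates 1 and 2 and high fat diet replicate 1, which stand apart, lie 2 against 1 in the real split, and of the 80 other splits that part them 2 against 1, 16 gave at least 1 gene and the highest gave 3. For genes in neuron subclusters 36 of 100 splits gave at least the real 2, with 10 in the highest other, so chance is not excluded there either, and 30 of the 83 that part the 3 mice alike gave as many. No explanation was tested for either result.

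Atp1b1 and complex I genes were higher in endothelial cells on the high fat diet, and so was neuron RNA in the same barcodes. An estimate from 10 neuron markers and the neuron profile of each mouse gave 108% of the rise of Atp1b1 (90.5 to 120% without each mouse in turn) and 105% of the rise of complex I CPM of all UMIs (94.5 to 119%). In fits with no filter on low counts, the log2 fold change of Atp1b1 was 1.51 with all barcodes, −0.12 without barcodes holding more marker UMIs of another class (SE 0.42, 390 cells, with 2 other genes passing) and −0.33 without barcodes holding any neuron marker UMI (SE 0.83, 174 cells), while complex I, tested as a list with the filter on, had a median of 0.42 over 16 subunits with all barcodes and 0.23 over 8 without the former barcodes (camera adjusted p = 0.181). A candidate explanation is a small number of barcodes that hold a neuron beside an endothelial cell, since barcodes with more neuron than endothelial marker UMIs numbered 3 of 269 in control mice and 6 of 167 in high fat diet mice and held 17.1% and 65.7% of Atp1b1 UMIs, but high fat diet replicates 2 and 6 held 0 of them, and in the latter 11 of 14 Atp1b1 UMIs lay in 2 barcodes richer in markers of another class that is not neurons. Per mouse such barcodes made up 1.58 ± 2.88% of endothelial barcodes in control mice and 3.73 ± 3.72% in high fat diet mice (SD, n = 6 each; exact permutation p = 0.286), so a difference in their frequency is not shown, and a rise of Atp1b1 in endothelial cells smaller than these SEs can show, or of complex I outside such barcodes, stays open.

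In endothelial barcodes the neuron markers were higher on the high fat diet in 10 of 10 (median log2 fold change 1.23), and other types moved apart, with oligodendrocyte markers higher in 10 of 10 (1.69), microglia markers in 5 of 6 (1.21), astrocyte markers in 4 of 9 (−0.17) and mural cell markers in 1 of 9 (−0.39). For single endothelial genes 5 of 100 splits gave at least the real count of 1, with 7 in the highest other, so chance is not excluded, and 2 of the 83 other splits that part the 3 mice alike gave as many, with 1 in the highest. For endothelial lists 2 of 100 splits, the real one included, gave at least the real count of 7, with 7 in the highest other. That was under the 5% set beforehand for this count taken alone. It was not adjusted over the counts tested, so chance is not excluded here either. Of the 83 other splits that part the 3 mice alike 1 gave 7, and all 7 calls were lost with an estimated correlation (adjusted p of 0.121 or more with an estimated correlation).

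Mitochondrially encoded and ribosomal protein genes were lower, and nuclear-encoded respiratory genes higher, as lists in several classes, with all of these calls lost with an estimated correlation (adjusted p from 0.121 to 0.756 with an estimated correlation). A shift of whole libraries that all classes of a mouse share is a candidate explanation, since 82.3% of the variance of the respiratory minus mitochondrially encoded score among mice of 1 diet lay between mice, against 12.9% at the 95th percentile of 10000 shuffles. Taking the trend over GC content and transcript length, 3.31 to 11.1% of the variance, from each library kept 10 of the 18 calls, and it argues against that trend as the whole cause of the ribosomal calls, all 5 kept and 4 of them with larger medians, of the mitochondrially encoded calls in oligodendrocytes, OPCs and microglia, all 3 kept at 76.3, 102 and 61.5% of their medians, and of the 2 nuclear respiratory calls in endothelial cells, both kept at 73.3 and 81.5%. The trend cannot be told apart from a diet difference for the mitochondrially encoded lists in neurons, with 0 of 2 calls kept and 73.5 and 92.5% of the medians left, or for the nuclear respiratory lists in neurons and astrocytes, with 0 of 6 calls kept and 30.2 to 87.8% left. A response of the cells to the diet stays open and was not tested apart from these.

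The lost calls by camera lay between complex I in glutamatergic neurons (median 0.07 with an interquartile range of 0.08 before and 0.06 with 0.06 after, adjusted p = 0.0708) and complexes III, IV and ATP synthase in astrocytes (0.11 with 0.22 before and 0.03 with 0.30 after, adjusted p = 0.694). The medians before the correction come from a fit limited to genes with a known GC content and length, so they can differ slightly from the list medians in Results. Mitochondrially encoded genes in GABAergic neurons lost their call with a median of −0.19 before and −0.18 after (interquartile ranges 0.19 and 0.21, adjusted p = 0.0878), a small move across the threshold. For lists over all classes 16 of 100 splits gave at least the real 28 calls, with 38 in the highest other and a median of 17 over the others, so chance is not excluded, and 12 of the 83 others that part the 3 mice alike gave as many.

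Grp and Rpph1 in GABAergic neurons had the smallest p of their class, and GABAergic subcluster 13 held 16 Grp UMIs in control mice and 179 in high fat diet mice. Without subcluster 13 the log2 fold change of Grp was 0.62 (SE 0.51), as a larger share of that subcluster would give, but a higher level inside it would give the same. The share of UMIs from subcluster 13 at a single Grp level gave 3.45% of the rise of Grp (−5.82 to 27.1% without each mouse in turn), which argues against a larger share of subcluster 13 itself as the cause. Grp UMIs also lay outside it. Control replicate 4 held 22 with 0 inside and control replicate 5 held 20 with 8 inside, while high fat diet replicate 4 held 80 with 44 inside. The share of subcluster 13 therefore does not measure the share of all Grp-rich cells, and a change in that was not tested. For Rpph1 a shift of whole libraries cannot be told apart from a change in GABAergic neurons, since glutamatergic neurons, the other class that measures it, gave 0.78 (SE 0.42), which did not pass, and the 6 non-neuronal classes held 113 UMIs. A higher Grp level inside subcluster 13 stays open, since the gene and the subcluster were singled out by the same counts, and the diet itself and other technical explanations were not tested.

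The counts of genes that differed by diet were 0 in the remaining classes by edgeR, and since each of the 100 splits must then give at least as many, these splits do not test chance. The highest other split gave 750 genes in glutamatergic neurons, 725 in GABAergic neurons, 149 in oligodendrocytes, 10 in OPCs, 6 in microglia, 2 in astrocytes and 2 in mural cells, beside 132, 156, 118, 48, 16, 19 and 6 genes at an unadjusted p under 0.05 in the real split. Among the splits that part the 3 mice 2 against 1 the highest were 1, 1, 1, 3, 2, 2 and 2 genes, in the same order. DESeq2 and limma voom with quality weights each gave 2 genes in GABAergic neurons and 0 in the rest. The splits with the highest counts in both neuron classes, oligodendrocytes, OPCs, microglia and mural cells placed control replicates 1 and 2 and high fat diet replicate 1 on the same side. This points to a structure of the samples that no label names as a batch, though these are the mice numbered 1 to 3, all in pool 1.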

How the results depend on the processing

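Of the tests below, those with a term for control replicates 1 and 2 and high fat diet replicate 1, without these 3 mice, without mixed barcodes, and without each mouse for neuron subclusters were chosen only after the result was seen. Of 569 alternative values 478 were kept, which for counts of genes or lists means equal to the main count or within 1.5 times of it and for shares and depth the same direction and side of the threshold, as were 5645 of 5925 values of named genes and called lists by direction and threshold, and for each change given here the cause was not tested unless the alternative itself shows it. Genes passing with no filter on low counts, which tests more genes, numbered 1 in glutamatergic neurons, 8 in GABAergic neurons, 2 in oligodendrocytes, 1 each in OPCs, microglia and mural cells, and 59 in endothelial cells, of which 10 are markers of other cell types, all higher, so RNA of other cells moves this count too. In GABAergic neurons 2 passed by DESeq2, by limma voom with quality weights, without a covariate and with the term for the 3 mice, and 1 with at least 1000 UMIs. In endothelial cells 2 passed by DESeq2, by voom and with DESeq2 size factors, 0 with at least 300 UMIs, at resolution 2, with doublets kept, with at least 30 cells per mouse and without mixed barcodes, 4 without the mice under 500 cells and 7 without the 3 mice. In mural cells 1, Fosb, passed with at least 300 UMIs, with the term and without mixed barcodes. The Ecel1 difference ended without the 3 mice (0 genes). Neuron subclusters gave 0 at resolution 0.5, 4 at resolution 2, 1 without a covariate and 8 with the term. Lists gave 0 calls with an estimated correlation and 4 by fry, against 28. Leaving out 1 mouse at a time gave 0 to 2 genes in GABAergic neurons, 0 to 1 in microglia (1 without high fat diet replicate 1), 1 to 7 in endothelial cells, 0 to 1 in mural cells (1 without control replicate 3 or high fat diet replicate 4), 0 to 1 for the difference between neuron classes, 0 to 8 in subclusters and 17 to 32 list calls (17 without high fat diet replicate 3). No share passed in any setting. Values changed sign as follows. With at least 1000 UMIs the difference of diets was 0.0225 in log10 median UMIs, 0.102 points in endothelial cells and −0.14 in microglia. With at least 300 UMIs it was −0.950 points in astrocytes and −0.0142 in fibroblasts, and at resolution 2 it was 0.604 in perivascular macrophages, beyond their whole share in the main clustering. Without the mice under 500 cells it was −1.21 in astrocytes, −0.146 in fibroblasts, 0.261 in hypocretin neurons, −0.16 in microglia and 0.0055 in perivascular macrophages, and without the 3 mice −0.263 in astrocytes and −0.00179 in glutamatergic neurons. Leaving out 1 mouse moved it from −1.23 to 0.805 in astrocytes, −1.55 to 0.397 in endothelial cells, −0.185 to 0.174 in fibroblasts, −0.249 to 0.295 in microglia and −0.0843 to 0.00752 in perivascular macrophages. Named genes that did not pass changed sign as follows, in log2 fold change. With at least 30 cells, and equally without the mice under 500 cells, glutamatergic neurons gave Hcrt 0.23, Pmch 0.043 and Nts 0.074, and GABAergic neurons Hcrt 0.21 and Scd2 −0.0086. By voom Hcrt was 0.15 and Nts 0.16 in glutamatergic neurons and Hcrt 0.51 in GABAergic neurons. In GABAergic neurons Pmch was 0.31 with at least 300 UMIs, Slc17a6 −0.15 at resolution 2, Slc32a1 −0.013 with the term and −0.030 without the 3 mice, and Hcrt 0.27 without them, as was mt-Nd2 in OPCs at 0.042. With at least 1000 UMIs endothelial cells gave Ndufa3 −0.19, Rps21 0.0040, Fosb 0.042, Klf4 0.0032 and Ldha −0.16. Leaving out 1 mouse gave in glutamatergic neurons Insr −0.70 to 0.036, Hcrt −0.38 to 0.16, Pmch −0.44 to 0.016 and Nts −0.39 to 0.11, and in GABAergic neurons Slc32a1 −0.041 to 0.10, Hcrt −0.48 to 0.17 and Gal −0.064 to 0.44. Depth was lowest in high fat diet replicate 7 and control replicates 6 and 7, and among classes in mural cells and microglia, whose smallest sums per mouse held 7985 and 13998 UMIs.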

Other observations

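The comparison of mixed barcodes between classes and the share of subcluster 13 are tests chosen only after the result was seen, as were the levels of Grp inside that subcluster. In mice with at least 4 cells of GABAergic subcluster 13, Grp stood at 40.6 ± 68.6 CPM of all UMIs of the subcluster in control mice (SD, n = 4) and 353 ± 175 in high fat diet mice (n = 6), with ranges of 0 to 143 and 179 to 640. The gene and the subcluster were singled out by these same counts, so no test of the difference is given. Over all mice the subcluster held 16 Grp UMIs in 47 control cells, 8 of them in control replicate 5, and 179 in 104 high fat diet cells. The subcluster held 4.75 ± 4.22% of GABAergic cells in control mice and 5.83 ± 1.08% in high fat diet mice (SD; exact permutation p = 0.611). Outside it Grp stood at 8.53 and 10.8 CPM.

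Neuron subclusters also held gene and subcluster pairs near the threshold that did not pass. In glutamatergic subcluster 9 Bdnf, a neurotrophin, had a log2 fold change of −1.19 (SE 0.22, edgeR adjusted p = 0.0549), at 653 ± 116 CPM in 3 control mice and 288 ± 121 CPM in 4 high fat diet mice (SD). Rpph1 in subcluster 5 was at 1.07 (edgeR adjusted p = 0.0763), Nefh in subcluster 5 at 0.93 (0.119) and Cartpt in subcluster 12, whose leading genes are Calca, Fezf1 and Trh, at 2.82 (0.119). In the test of the difference between neuron classes Lhx1 was at 0.91 (edgeR adjusted p = 0.282) and Fos at −0.73 (0.677).

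Barcodes with more marker UMIs of another class than of their own made up 6.32% of endothelial barcodes in control mice and 15% in high fat diet mice (exact permutation p = 0.11 over mice), and 2.65 and 0.510% of astrocyte, 0 and 0.463% of microglia and 0 and 0% of oligodendrocyte barcodes. Neuron RNA was estimated at 8.52% of astrocyte UMIs in control mice and 8.04% in high fat diet mice (exact permutation p = 0.866), 3.97 and 3.40% in oligodendrocytes (p = 0.446), 3.52 and 4.83% in microglia (p = 0.249) and 7.54 and 6.76% in mural cells (p = 0.866).

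Over the 91 pairs of mice, counts differed by 2.67 to 45.5 times their sampling variance, so no pair looks like the same library sequenced again.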
